A study of Solanum lycopersicum with 2 samples.

How the data were processed

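Total RNA of tomato leaves was enriched for small RNA, cut from a gel at 15 to 30 nt, ligated to adapters, amplified and sequenced on an Illumina Genome Analyzer II, per the labels' protocols. There was 1 library from healthy leaves and 1 from leaves of plants inoculated with cloned tomato leaf curl New Delhi virus, and the groups were taken from the labels. Each deposited file lists distinct sequences with a count, the number of reads with exactly that sequence, with no normalization. Bowtie is named in the submitters' processing notes without version or role. How adapters were trimmed, which quality or length filters were used and which genome build was matched are not given in the sources used here. Sequences ranged from 5 to 25 nt, so inserts of 26 to 30 nt are either missing or shown clipped. The reads carry no molecular identifiers, so intervals and floors cover counting error only and not the variation between plants or library preparations.

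Reads below 15 nt, 0.114% of the library labelled healthy and 0.194% of the library labelled infected, entered the library totals, the counts of distinct sequences and the shares read once, and were left out of length shares and miRNA counts. Reads were scaled to RPM, reads per 1000000 reads of the library total, and 3 reads, taken as the floor, correspond to 0.418 and 0.471 RPM. Shares have exact Clopper-Pearson intervals, RPM values exact Poisson intervals and ratios exact conditional binomial intervals, all at 95%. With 1 library per group no test between conditions was possible, and no p-value was computed.

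miRNA sequences were written from general knowledge of tomato and other plant miRNAs before the data were examined, in 37 families grouped in 5 lists. They were not taken from a database release, so a family without reads can also mean that the tomato sequence differs from the listed one. A read was assigned to a listed sequence when the part more than 3 nt from either end matched exactly and neither end moved by over 3 nt. Reads that fitted 2 families equally well were to be left out, and there were 0 such reads in both libraries. Every family with at least 100 reads in one library was named, up to 25. A family was called when it differed at least 2-fold with an interval excluding 1. The rule also allowed other tags that matched the genome, but no genome sequence was used, so none was named. Lists were compared with 10000 random lists of other 20- to 22-nt tags with at least 20 reads, each drawn from the 200 tags nearest in abundance, with 0.5 reads added to each count. A table of tomato gene names (assembly SLM_r2.1) was used only to count annotated loci, and no coordinates are given since the authors' build is not known.

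End classes were assigned in order: exact, 5′ end changed, 3′ end shorter, 3′ end longer, 3′ end substituted. Added and lost single bases were counted for listed sequences with at least 1000 exact reads, against single substitutions at interior positions of the same sequences. A base could not be called non-templated without a genome. The planned share of reads that match the genome and annotated features was likewise not computed. Fragments of 8 ribosomal and transfer RNAs were counted by exact match to sequences written from general knowledge after the data were examined, so their levels are minimum values. Adapter-derived reads were those matching at least 12 nt of the end of the 5′ adapter of the Illumina small RNA kits, or ending in its last 16 nt.

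Begomovirus-like reads were sought as translated windows of 7 residues of conserved peptides and as 16-nt windows of degenerate primer sites, written from general knowledge before the data were examined. Whole coat and replication-associated proteins were added afterwards. The same sequences reversed gave the background. Only reads of at least 21 nt can hold a peptide window, and reads of a virus whose proteins differ from the listed ones are missed, so the counts are no measure of viral load. Tags with at least 3 reads were joined into contigs of at least 60 nt by unambiguous overlaps of 17 nt.

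Alternatives listed before the data were examined were a median-of-ratios factor and a TMM factor (edgeR 4.0.16) over 20500 tags with at least 10 reads in both libraries, scaling to the miRNA reads, exact sequences only, end changes of up to 1 nt, omission of sequences read once, other length windows, and other ways of pooling end changes. On simulated counts for 5990 tags with 200 changed, 95.9% of intervals held the true ratio. The rule called 100% of tags at a true ratio of 3 and 96% at 0.333, 8% at 1.5 and 4% at 0.667, and 0.0345% of unchanged tags. Both simulated libraries were Poisson draws from the same levels apart from the set changes, without variation between plants or preparations. These rates therefore check the computation only and are not error rates for the real libraries. Assignment recovered the family and both ends for 99.8% of 2000 simulated reads. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.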

Results

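Small RNAs were sequenced from leaves of tomato (Solanum lycopersicum) cultivar Pusa Ruby, which the labels describe as susceptible to tomato leaf curl virus (ToLCV). ToLCV is a begomovirus, a geminivirus with a circular single-stranded DNA genome that is carried between plants by whiteflies. The study compared healthy leaves with leaves of plants inoculated through Agrobacterium with cloned viral genomes, and its title names changes at both ends of mature microRNAs (miRNAs) as the subject. There was 1 library per group. No difference below therefore has a replicate check, and each interval is a 95% interval that covers counting error only. The library labelled healthy held 7182448 reads in 3831219 distinct sequences, and the library labelled infected held 6374617 reads in 3752928. Sequences read once made up 82.8% of the distinct sequences of the first and 85.5% of those of the second.

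Reads that resembled a begomovirus were found mainly in the library labelled healthy, against its label. Peptides of begomovirus proteins listed before the data were examined matched 11 reads there (interval 5.49 to 19.7) and 1 read in the library labelled infected (0.0253 to 5.57), while the same peptides read backwards matched 2 and 3 reads. Sites of degenerate begomovirus primers matched 10 and 3 reads, and the reversed sites 1 and 2. With windows over whole coat and replication-associated protein sequences, chosen after seeing the data, 120 distinct sequences with 167 reads matched in the library labelled healthy and 18 sequences with 18 reads in the library labelled infected. The reversed proteins matched 15 sequences with 68 reads and 14 sequences with 22 reads, so a part of the matching reads is background and the shares below include it. Of the 167 reads, 59.3% were 22 nt long (51.4% to 66.8%) and 19.8% were 21 nt (14.0% to 26.6%). A further 13.2% were 24 nt (8.44% to 19.3%). These are lengths of plant Dicer products, but only reads of at least 21 nt could match. Reads over 21 nt can hold a window in more reading frames, which may inflate the 22-nt share relative to the 21-nt share. This does not account for the lower share at 24 nt. No length profile was made for matches of the reversed proteins, so the lengths do not tell viral reads from background. Both strands were present, with 55.1% of the 167 reads in the sense orientation (47.2% to 62.8%). The conserved geminivirus nonanucleotide, a motif short enough to occur by chance, was in 469 and 428 reads. No assembled contig of at least 60 nt carried a listed motif in either library. Only tags with at least 3 reads were assembled, and no tag with a primer site had over 2 reads. In the library labelled infected no tag with a listed peptide or primer site had over 1 read. The primer result was therefore fixed in advance, and the absence of motifs says little about viral contigs. Because these reads go against the labels, the libraries are called "labelled healthy" and "labelled infected" throughout, and every direction given below is a direction between labels.

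In both libraries 24-nt reads were the largest class and 21-nt reads a smaller peak. The 24-nt class, which in plants consists mostly of heterochromatic small interfering RNAs, took 38.7% of the reads of at least 15 nt in the library labelled healthy (38.6% to 38.7%) and 42.4% in the library labelled infected (42.4% to 42.5%). The 21-nt class, to which most miRNAs belong, took 17.7% and 14.8%, and the 22-nt class 14.8% and 12.8%. Reads of 23 nt were nearly as frequent as 21-nt reads, at 17.5% and 14.5%. Among distinct sequences the 23-nt class came next after 24 nt, with 21.5% and 18.3%, and the 21-nt class held 12.1% and 10.0%. Reads of 25 nt, the longest in either file, were 1.91% of the first library and 6.32% of the second, a ratio of 3.30 in RPM (reads per 1000000 reads of the library) (3.28 to 3.33). When sequences read once were left out, the 24-nt shares were 37.0% and 37.7%.

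**Figure D1:**
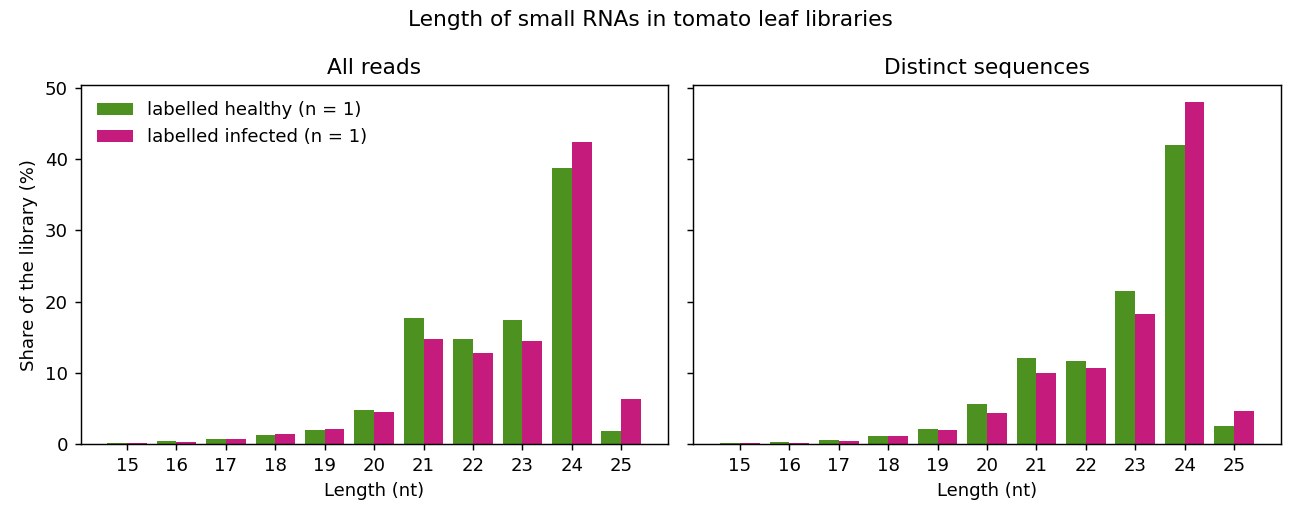
Share of each library (vertical axis, percent of reads or of distinct sequences of 15 to 25 nt) by length in nt (horizontal axis), for the library labelled healthy and the library labelled infected, 1 library each. The 24-nt class is the largest in both (38.7% and 42.4% of reads), and the 25-nt class takes 6.32% of reads in the library labelled infected against 1.91% in the other.

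The first base followed the length class in both libraries. Argonaute proteins sort small RNAs partly by this base, AGO1 taking mostly uridine and AGO4 mostly adenosine. Uridine led 50.1% of 21-nt reads in the library labelled healthy (50.0% to 50.2%) and 45.5% in the library labelled infected (45.4% to 45.6%), and it led 44.0% and 42.4% of 22-nt reads. Adenosine led 70.0% of 24-nt reads in the first library (70.0% to 70.1%) and 67.5% in the second (67.4% to 67.5%). Among distinct 21-nt sequences adenosine was the most frequent first base, at 40.1% and 40.7%, and uridine led 30.4% and 30.2%. The leading pair of miR166 sequences supplied 155366 and 59261 of the 635799 uridine-led 21-nt reads in the library labelled healthy. In the library labelled infected the same pair supplied 57222 and 32820 of 427191. The difference in the uridine share of 21-nt reads therefore rested largely on this miRNA.

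Listed miRNAs took 5.12% of the reads in the library labelled healthy (5.11% to 5.14%) and 3.05% in the library labelled infected (3.03% to 3.06%). The miR166 family, which includes miR165 and targets class III HD-ZIP transcription factors of leaf polarity, supplied 63.2% of the miRNA reads in the first and 51.7% in the second. Of 37 families listed before the data were examined, 34 had at least 1 read and 24 had at least 100 reads in one library. Among these 24, a family was called when it differed at least 2-fold with an interval excluding 1. By this rule 7 families were higher in the library labelled infected, 1 was lower and 16 were not called. Counts were scaled to all reads of the library. Scaling to miRNA reads raised every ratio by a factor of 1.68 and took the number called higher to 14. Most of these miRNA reads were miR166, so the factor depends on the level of that family. The single call of a lower family was lost under each of the alternatives tried.

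Among families that target developmental regulators, 4 of 12 were called higher in the library labelled infected and 1 lower. miR160, which targets the auxin response factors ARF10, ARF16 and ARF17, rose from 23.4 to 95.8 RPM, a ratio of 4.10 (3.45 to 4.89). miR396, which targets growth-regulating factors, had a ratio of 2.56 (2.37 to 2.77), and miR164, which targets NAC transcription factors, 2.29 (2.16 to 2.42). miR169, which targets NF-YA subunits, had only 34 and 106 reads and a ratio of 3.51 (2.37 to 5.33). Its call was lost when only exact sequences were counted, with a ratio of 1.29. The miR166 family was the most abundant, with 32386 and 15750 RPM, and its ratio was 0.486 (0.483 to 0.490). This value lay close to the 2-fold limit. It reached 0.817 when scaled to miRNA reads, but the family itself supplied 63.2% and 51.7% of those reads. That scaling therefore compares the family largely with itself. The other abundant families stood just inside the limit, miR167 at 0.559 (0.551 to 0.568) and miR156, counted with miR157, which targets SPL factors of phase change, at 0.522 (0.510 to 0.534). Not called with ratios above 1 were miR171 (1.84), miR159 (1.78), miR394 (1.58), miR172 (1.35) and miR390 (1.31). Of these, miR171 and miR159 stayed uncalled under only 3 of 7 alternatives and were called higher under the others. The miR390 value depended on the form counted. Its exact listed sequence alone gave 3.71 and would be called higher. Its most abundant form over both libraries had 0.484 (0.4575 to 0.5115) and would be called lower. The median log2 ratio of the 14 families of this list with at least 20 reads was 0.85, at percentile 96.8 of 10000 random lists of other tags matched on abundance, which describes these 2 libraries and tests nothing between conditions. The random lists centred below 0, at -0.22 here and from -0.39 to -0.15 over the 5 lists. Percentiles here and below are therefore not measured against no change. A family also sums its end variants, whereas each random tag is 1 sequence.

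Of the families that target disease resistance genes of the NLR class or receptor-like proteins, 2 of 6 were called higher in the library labelled infected and none lower. miR6024 had a ratio of 2.67 (2.48 to 2.88), which was 17.1 with the exact listed sequence alone while its most abundant form over both libraries had 0.827. For miR482, an initiator of secondary small RNAs from NLR transcripts, the ratio was 2.01 (1.86 to 2.17). This call stood at the limit, and exact sequences alone gave 1.99. Within that family, miR482b had a ratio of 3.24 (2.87 to 3.66) and miR482e 1.26 (1.096 to 1.45). miR6027 went the other way without being called, at 0.531 (0.516 to 0.547). The ratios of miR6023 (1.68) and miR6022 (1.16) were above 1 and that of miR5300 was 0.938 (0.887 to 0.991), which turned above 1 under 3 of 4 other scalings. The median log2 ratio of the list was 0.48, at percentile 77.6 of random lists.

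No named family of the silencing pathway was called. miR168, which targets AGO1, had 2327 and 1719 RPM and a ratio of 0.739 (0.721 to 0.757), which became 1.24 when scaled to miRNA reads. miR162, which targets DCL1, had a ratio of 1.23 (1.13 to 1.34). miR6026, which targets DCL2 and is named here outside the rule and after its values were seen, had 55 and 83 reads and a ratio of 1.70 (1.19 to 2.44). These 3 families had a median log2 ratio of 0.30, at percentile 66.8. No read of miR403, which targets AGO2, was counted in either library, where 3 reads would be 0.418 and 0.471 RPM. miR6019 and miR828 also had no reads.

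The 1 named family of the nutrient and copper list was miR827, which targets SPX genes of phosphate homeostasis. It had 45 and 104 reads and was called higher in the library labelled infected, with a ratio of 2.60 (1.82 to 3.78). The 5 families of this list with at least 20 reads had a median log2 ratio of 1.37, at percentile 94.5 of random lists. With exact sequences only the median was 0.41, over families with at least 20 exact reads, which left out miR408 with 0. Of the remaining named families, miR4376 had a ratio of 1.17 (1.11 to 1.22), tasiARF, a trans-acting small RNA made from TAS3 transcripts, 0.689 (0.600 to 0.790), and miR1919 0.596 (0.443 to 0.797). Both of the latter turned above 1 when scaled to miRNA reads, at 1.158 for tasiARF and 1.001 for miR1919. Exact sequences only also did so, with 1.53 (1.16 to 2.02) for tasiARF and 1.10 (0.706 to 1.72) for miR1919. With end changes of up to 1 nt both stayed below 1, at 0.549 and 0.590. None of these 3 was called, and the list had a median log2 ratio of -0.16, at percentile 52.7 of random lists with a median of -0.23.

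**Figure D2:**
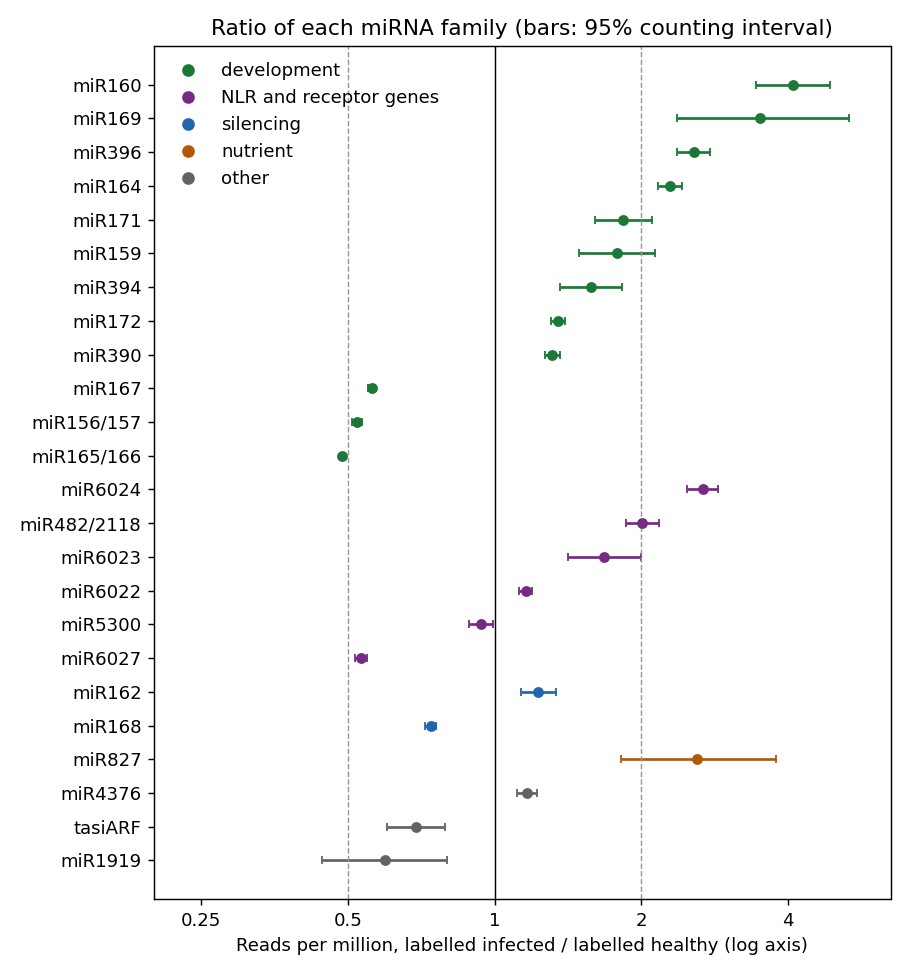
Ratio of RPM, labelled infected over labelled healthy, for each of the 24 named families (log axis), coloured by the list fixed before the data were examined. Points are ratios between 1 library and 1 library, bars the 95% counting interval, and dashed lines mark 2-fold. miR160 stands farthest to the right at 4.10, and miR166 at 0.486 is the only family left of the lower dashed line. Under other scalings miR168, miR1919, tasiARF and miR5300 change side of 1, and miR1919 and tasiARF also do with exact sequences only.

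By reads, changes at the 3′ end alone outnumbered changes at the 5′ end in both libraries. Over distinct sequences, 3′ changes with an unchanged 5′ end were 44.2% and 42.2%, and changed 5′ ends 52.4% and 54.8%. The latter class also holds sequences changed at both ends, so these shares do not tell which end changed more often. Of the miRNA reads, 46.6% in the library labelled healthy and 56.4% in the library labelled infected had exactly a listed sequence. Reads with an unchanged 5′ end and a changed 3′ end were 50.5% (50.4% to 50.7%) and 38.7% (38.5% to 39.0%), and reads with a changed 5′ end 2.90% (2.85% to 2.96%) and 4.85% (4.75% to 4.94%). Most of the 3′ total came from 1 sequence of miR166, TCGGACCAGGCTTCATTCCTC, which differs from the listed sequence near its 3′ end and had 155366 and 57222 reads. Without the miR166 family, 3′ changes were 14.0% (13.9% to 14.2%) and 13.4% (13.2% to 13.6%), and 5′ changes 3.19% (3.10% to 3.29%) and 4.95% (4.81% to 5.09%). Of the latter reads, 4320 and 4648, miR6024 alone gave 84 and 1026. Not every family shared the direction of the 5′ difference, and miR156, counted with miR157, had 5.84% and 3.60%. The direction of the 3′ difference turned in the median over families, with 7.73% and 10.7%, and when the most abundant sequence of each member served as the reference, with 23.4% and 27.6%, an alternative chosen after seeing the data. No genome was used, so a base encoded by another gene copy and a base added after processing were counted alike.

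Single bases added to the 3′ end were mostly adenosine. Over members with at least 1000 exact reads, 13 in each library and 12 of them shared, sequences with 1 added base amounted to 3.42% of the exact reads in the library labelled healthy and 3.36% in the library labelled infected. Adenosine made up 78.2% and 73.1% of these, cytidine 14.9% and 18.7%, uridine 6.76% and 8.11%, and guanosine 0.104% and 0.115%. The adenosine came almost wholly from miR167, where TGAAGCTGCCAGCATGATCTAA had 4379 and 2436 reads against 40813 and 19930 exact reads. The cytidine came largely from miR168, with 714 and 586 reads of TCGCTTGGTGCAGGTCGGGACC. Per member the share with 1 added base was 11.2% and 12.7% for miR167, 4.72% and 5.98% for miR168, and 2.999% and 1.87% for miR4376. Added bases other than the leading one of each member together reached 0.207% of exact reads in both libraries, beside a background of single substitutions at interior positions with a median of 0.147% and 0.190% per position. One added base at the 5′ end reached 0.370% and 0.331%.

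Shortening was also specific to the miRNA. Loss of 1 base from the 3′ end reached 15.9% and 17.7% of exact reads for miR6027, against 1.94% and 1.88% over all 13 members. Loss of 2 bases reached 13.1% and 7.47% for miR166, where the shortened sequence can come from either of its leading forms. For miR4376, 27.6% of reads in the library labelled healthy (26.1% to 29.2%) and 33.1% in the library labelled infected (31.5% to 34.7%) had a changed 5′ end.

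The shares of the sequences within some families differed between the libraries, and in miR390, miR6024 and miR482 another sequence was the most abundant. For miR390, which cuts TAS3 transcripts, AAGCTCAGGAGGGATAGCACC was 70.1% of family reads in the library labelled healthy (68.9% to 71.2%) and 25.8% in the library labelled infected (24.8% to 26.8%). AAGCTCAGGAGGGATAGCGCC went from 23.3% (22.3% to 24.4%) to 65.8% (64.6% to 66.9%). These forms differ by A19G, counted from the 5′ end. For miR6024, TTTTAGCAAGAGTTGTTTTCCC was 83.02% (80.6% to 85.3%) and 25.7% (23.9% to 27.5%), while TTTTAGCAAGAGTTGTTTTACC, which differs by C20A, was 3.75% (2.67% to 5.11%) and 24.1% (22.4% to 25.8%). A form of the latter that starts 1 base later, TTTAGCAAGAGTTGTTTTACC, was 4.64% and 36.0%, the most abundant in the library labelled infected. The family ratio of miR6024 thus combined forms with ratios of 0.827 (0.744 to 0.918), 17.1 (12.3 to 24.5) and 20.8 (15.5 to 28.5). In miR482 the leading sequences are separately listed members of the family, not end variants of each other. There miR482e, TCTTTCCTACTCCTCCCATACC, was 36.0% and 21.9% and miR482b, TCTTGCCTACACCGCCCATGCC, 31.9% and 50.7%. In miR396, the listed member miR396a, TTCCACAGCTTTCTTGAACTG, led in both libraries, with 48.0% and 71.5% of family reads. In miR172, AGAATCTTGATGATGCTGCAT led in both, with 76.1% and 67.9%, and AGAATCTTGATGATGCTGCAG was 14.5% and 21.99%. By contrast, the exact sequence of miR160 held 95.2% and 95.3%, and that of miR164 92.1% and 92.0%.

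**Figure D3:**
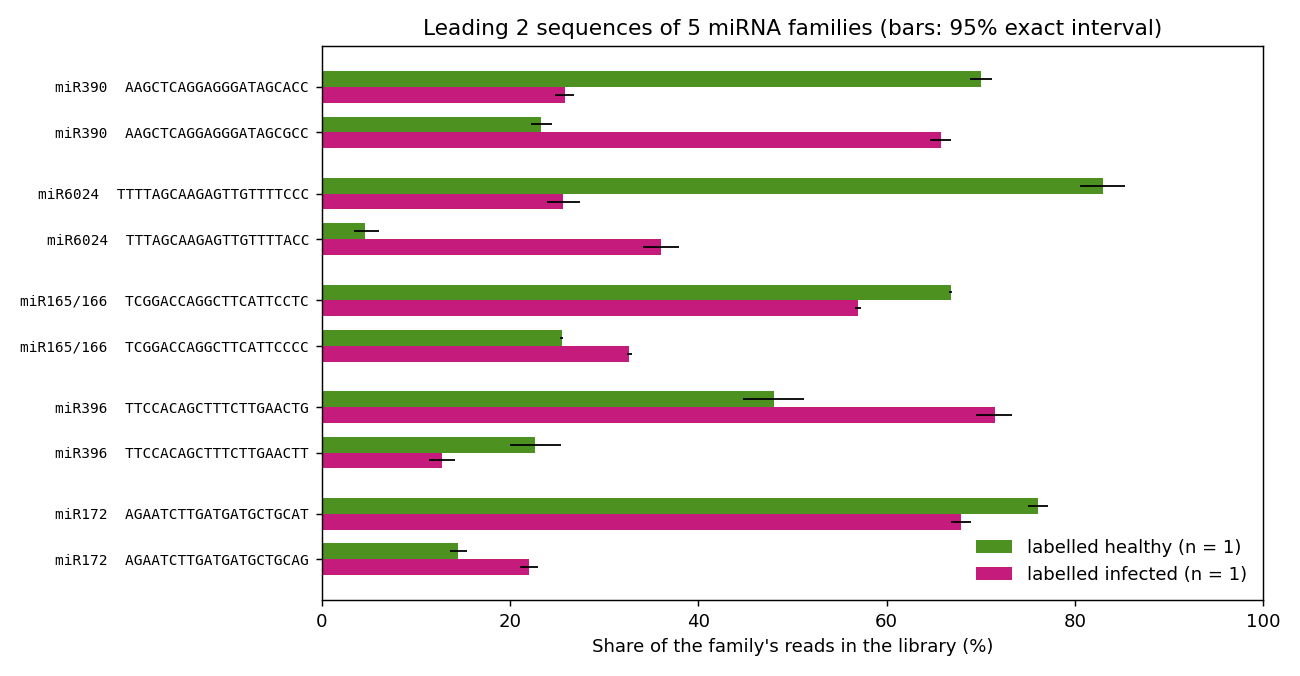
Share of the family's reads (percent, horizontal axis) held by the leading pair of sequences in 5 miRNA families, for the library labelled healthy and the library labelled infected, 1 library each, with exact 95% intervals as black bars. In miR390 the sequence ending in CACC holds 70.1% and 25.8%, and the sequence ending in CGCC 23.3% and 65.8%.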

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

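All tests in this part were chosen after the results were seen, and with 1 library per group none of them compares conditions.

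The library labelled healthy held 167 reads in 120 distinct sequences with windows of begomovirus coat or replication-associated protein, a signal outside the tomato small RNAs that was expected in the other library. Chance matches are argued against, since the reversed proteins matched 15 sequences of the same library, although with 68 reads, and a file reduced to reads of the tomato genome is argued against by the 29537 adapter-derived reads left in the library labelled infected. An exchange of the labels is not excluded, as the library labelled infected held 18 matching sequences against 14 for the reversed proteins, but these counts are the pattern itself and give it no support. Sequences of 20 to 24 nt with at least 50 reads that were found in 1 library only, 183 in the library labelled infected and 18 in the other, and contigs of at least 60 nt, 114 and 60, would go with the labels if they came from a virus. The origin of these sequences was not determined. No contig carried a listed motif, but no tag with a primer site reached the 3 reads needed to enter the assembly. An exchange therefore cannot be told apart from virus carried by the plants sampled as healthy. In that case viral reads of the other library could be absent, or be missed because their proteins differ from the listed ones.

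Reads of 25 nt were 6.32% of the library labelled infected against 1.91% of the other, and 8 ribosomal and transfer RNAs gave 26200 of its 402230 reads of this length against 4141 of 137129. A higher level of such fragments at every length is argued against as the whole cause, because the 8 RNAs together had a ratio of 1.47 (1.46 to 1.49) at 18 to 23 nt and of 7.13 (6.90 to 7.37) at 25 nt. Without 5.8S ribosomal RNA, the only one below 1 at 18 to 23 nt, these were 2.075 (2.047 to 2.104) and 7.645 (7.333 to 7.972). Single RNAs reached 5.16 at 18 to 23 nt, yet for each of the 8 the upper bound there was under 50% of the lower bound at 25 nt. If fragments longer than 25 nt were clipped and kept in one file and mostly left out of the other, the number of 25-nt over 24-nt reads should be higher there for each RNA, and it was for 8 of 8, with 5.03 against 1.096 over all of them. This restates the excess at 25 nt on RNAs listed after the data were seen, so it gives no support to a difference in the handling of longer inserts. That explanation cannot be told apart from longer fragments in the leaves of the library labelled infected, which were not tested, as neither file holds reads over 25 nt.

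Adapter-derived reads were 0.463% of the library labelled infected (0.458% to 0.469%) against 0.126% of the library labelled healthy (0.123% to 0.128%), a signal that is no plant RNA.

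Among sequences of 20 to 24 nt with at least 50 reads, 183 of 3732 in the library labelled infected had no read in the other library, and 107 of these were 22 nt long. In the library labelled healthy the number was 18 of 5633.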

How the results depend on the processing

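The scaling to library totals, the use of end variants and the pooling of families set how many families were called and how large the end-change shares were. Alternatives chosen after seeing the data were the total without adapter-derived and 25-nt reads, the most abundant sequence of each member as its reference, and the whole-protein windows. No paired analysis was possible because each group had 1 library. The cause of the shifts below was not tested except where the construction of the alternative gives it. Relative to library totals, every log2 ratio moved up by 0.21 with the median-of-ratios factor, 0.24 with TMM and 0.75 with scaling to miRNA reads. Leaving out sequences read once changed the totals by 0.17 on this scale and also removed reads of each family.

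The number of families called higher was 7 and became 14 when scaled to miRNA reads. Under the other 6 alternatives it ranged from 6 to 9. All 7 kept their call under each change of scaling, and 5 of them did with exact sequences only or with end changes of up to 1 nt, where miR169 (1.29 and 1.79) and miR482 (1.99 and 1.98) lost it. Exact sequences and end changes of up to 1 nt moved miR390 from 1.31 to 3.71 and 3.72, which would be called, and miR6024 from 2.67 to 17.1 and 19.9. Exact sequences moved tasiARF from 0.689 to 1.53 and miR1919 from 0.596 to 1.10, whereas end changes of up to 1 nt gave 0.549 and 0.590. The number called lower went from 1 to 0 under all 7 alternatives, as miR166 moved from 0.486 to values of 0.511 to 0.817. The value of 0.817 came from scaling to miRNA reads, most of which were miR166 itself. Over the 24 families and 7 alternatives, 83 of 168 ratios stayed within the main interval or kept their call, 59 moved beyond the interval, 15 became called, 11 lost a call, and 0 called families changed direction.

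The median log2 ratio of the lists, first with the median-of-ratios factor and then with exact sequences, was 1.06 and 0.61 for development, 1.58 and 0.41 for nutrient and copper, 0.51 and 0.31 for silencing, 0.69 and 0.40 for NLR and receptor targets, and 0.049 and 0.37 for the others, whose main value was -0.16.

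Length shares in the libraries labelled healthy and infected were 17.96% and 14.94% (21 nt) and 39.25% and 42.93% (24 nt) over 18 to 26 nt. With sequences read once left out they were 22.06% and 19.61%, and 36.97% and 37.7%, and first-base shares were 58.77% and 53.66% (uridine, 21 nt), 49.46% and 47.71% (uridine, 22 nt), and 75.4% and 72.52% (adenosine, 24 nt). The difference between the libraries kept its direction in each. No setting left out miR166, on which the uridine difference at 21 nt largely rested.

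The shares of 3′ changes, 50.5% and 38.7%, became 44.15% and 42.2% over distinct sequences, 7.727% and 10.69% as the median over families, 49.63% and 37.3% with up to 2 nt, 14.05% and 13.43% without miR166, and 23.44% and 27.59% with the most abundant sequence as reference. The median and the last turned the direction. The shares of 5′ changes, 2.90% and 4.85%, became 52.39% and 54.83%, 2.351% and 3.31%, 2.73% and 4.597%, and 3.195% and 4.95% under the first 4 of these, and kept their direction in all 5. Window reads of begomovirus proteins went from 11 and 1 to 167 and 18 with whole proteins. Contigs with a motif stayed at 0 in both libraries with tags of at least 10 reads. No tag with a listed peptide or primer site had over 4 reads, so this setting checks little.

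Genome-matched scaling, genome-matched length shares and mismatches to viral contigs were not run, as no genome was used and no contig carried a listed motif. Few reads widen the counting interval, as for miR169 with 34 and 106 reads (2.37 to 5.33). Whether depth set its loss of the call was not tested, and miR827, with 45 and 104 reads, kept its call under 7 of 7 alternatives.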

Other observations

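All tests in this part were chosen after the results were seen.

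Families outside the naming rule, described after their values were seen, numbered 13, of which 9 had reads in both libraries. Of these, 8 had a ratio above 1 and 5 an interval wholly above 1, with 0 wholly below. miR398, which targets copper/zinc superoxide dismutases, had 7 and 60 reads, a ratio of 9.66 (4.41 to 25.05). miR408, which targets plantacyanins and laccases, had 3 and 31 reads, a ratio of 11.6 (3.63 to 59.5), and none of them had exactly the listed sequence. In the same list, miR397 had 50 and 48 reads and a ratio of 1.08 (0.713 to 1.64), but its exact sequence had 18 and 3 reads, a ratio of 0.188 (0.0354 to 0.643). miR399 had 30 and 20 reads, a ratio of 0.751 (0.404 to 1.37), and miR395 had 5 reads in each library. miR393, which targets the TIR1/AFB auxin receptors, had 14 and 31 reads, a ratio of 2.49 (1.29 to 5.08), and miR530 35 and 73 reads, a ratio of 2.35 (1.55 to 3.62).

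At 18 to 23 nt, 7 of the 8 structural RNAs had a ratio above 1 with an interval excluding 1, up to 5.16 (4.72 to 5.64) for a transfer RNA for glycine. Only 5.8S ribosomal RNA was lower, with 27042 and 18408 reads of these lengths, a ratio of 0.767 (0.753 to 0.782). One 21-nt sequence outside the miRNA list, TTGGCTGAGTGAGCATCACGG, chosen after its values were seen, had 1950 and 10493 reads, a ratio of 6.06 (5.78 to 6.37), and its origin was not determined.

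The shares of the forms of miR390 that differ by A19G, and of those of miR6024 that differ by C20A, differed between the libraries. Sequencing errors at the rate of interior positions are argued against. The rarer form relative to the commoner was at least 11.2 times the 90th percentile of substitutions at interior positions, the smallest of the 4 values. Position 19 of miR390 and position 20 of miR6024 lie just outside the interior positions, and the error rate there was not measured. A form missing from the plants of one library would need its reads there to be carried over from the other library. For the 38 reads of TTTTAGCAAGAGTTGTTTTACC in the library labelled healthy that share is 6.57%, which predicts 31.1 reads for the most abundant 20- to 24-nt sequence of the library labelled infected that had 0 reads there, and this was the smallest prediction of the 4 cases. Such a missing form is therefore argued against, provided that all sequences carry over alike. A difference in the expression of gene copies, or plants that differ in copy number or carry a mixture of alleles, may underlie the shift, and the design with 1 library per group leaves these open.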
